A study of Mus musculus with 2 samples.

How the data were processed

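The data are peak lists from ATAC-seq of mouse limb tissue at embryonic day 13.5, in 1 group of 2 biological replicates with separate biosamples, per the labels. The labels give tagmentation with the Nextera enzyme and a fragment size range of 200 to 750 bp. The deposited lists are on the mm10 build, and the deposited texts beside them say which filtered alignments each list was derived from, with a second input to the thresholded and looser lists that they do not describe. The aligner, the peak caller, their versions, the treatment of the transposase offset and the read filters are not given in the sources used here. The authors called peaks for each replicate and for the pooled libraries. For each replicate there was a list thresholded on the irreproducible discovery rate (IDR) and a looser list called pseudoreplicated. For the pooled libraries there were an IDR-thresholded, a conservative IDR-thresholded, a pseudoreplicated and a replicated list. Lists of entries ranked by IDR were also used.

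In the deposited lists, the enrichment of each peak is a signal value of the authors' peak caller, and what it is relative to is not given in the sources used here. Each peak also has a −log10 p-value by the authors' caller, and the ranked lists have a −log10 global IDR. The deposited display score runs from 0 to 1000 and was used only to check the IDR threshold. An enrichment was used to describe and rank peaks within its own list. The thresholded lists held the ranked entries at an IDR of 0.05 or less, minus between 158 and 192 entries per list. Peak lists give no read counts, so the depth of each library is unknown, no counting interval is given, and a region missing from a list may be open below the threshold.

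Several deposited entries, each with its own summit, shared an interval. Entries that overlapped were merged into regions, and each region was represented by its summit of highest enrichment. Chromosomes 1 to 19, X and Y were used, and the gene tests left out Y. Gene annotation was GENCODE M21 with the GRCm38.p6 sequence, the same assembly as mm10, and all intervals were checked to lie inside its chromosomes. A promoter was the stretch within 1000 bp of the start of any annotated transcript (132633 distinct starts), and other regions were called distal. A gene had a promoter region when any region overlapped the promoter of any of its transcripts, which can also be the promoter of a neighbour. Distal regions were assigned to the protein-coding gene with the nearest 5′ end.

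Overlap between the replicates needed at least 1 bp and was set against 100 random placements on the same chromosome. Gene lists were compared with other protein-coding genes (21728 in all) by the share with a promoter region in both replicates, with a two-sided Fisher's exact test and Benjamini-Hochberg adjustment over the 18 lists. The 18 lists covered limb patterning, posterior Hox genes, Hoxb and Hoxc genes, cartilage, bone, joint and tendon, muscle, ectoderm, endothelium, red blood cells, leukocytes, Schwann cells and melanoblasts, neurons, liver, heart, lung with gut and pancreas, germ cells with photoreceptors, and housekeeping genes. They held 334 distinct genes found in the annotation, and Ahsp was not found. Distal regions per gene were compared with 10000 random lists matched in 20 bins on the length of DNA nearest to the gene, by a two-sided permutation test whose smallest p is 0.0002. For motifs, windows of 100 bp on each side of the summit were compared with windows centred 1000 bp to each side that overlapped no peak of any list, by Fisher's exact test with adjustment over 31 motifs. A motif was called when it passed in the same direction in both replicates, and no ratio is given where no flank held it. Promoter and distal strength were compared by a permutation test with 100000 resamples within each replicate. A value given as mean ± SD is over the 2 replicates.

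The lists, motifs, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule took, for each list, up to 3 genes with the strongest promoter regions in the pooled list and up to 3 without one in either replicate in alphabetical order. It also took the 10 genes with the most distal regions, a fixed set of limb and control genes, the 5 strongest pooled peaks and the 5 densest windows of 1 Mb. Other genes named were chosen after their values were seen. The alternatives were other promoter windows (500 bp, or 2500 bp upstream), coding transcripts only, the gene's 5′ end only, the pseudoreplicated, pooled and conservative lists, the stronger 50% of each list, a background without the other listed genes and the olfactory and vomeronasal receptor genes, a reciprocal overlap of 50%, a summit inside the other region, equal list lengths, −log10 p-values as strength, motif windows of 50 bp, dinucleotide-preserving shuffles, distal regions within 50 kb, unmatched random lists, and each replicate alone. A count of every summit and the exclusion of promoter regions shared between coding genes were added after seeing the data.

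The list tests were tested on simulated data. Planted lists had 95% of their genes given a promoter region, against 60% of 21728 genes. Of the planted lists, 86.7% were recovered, and 1.25% of unchanged lists were called. Only raised lists were simulated, so recovery of lowered lists was not tried. In the data, 45.9% of genes had a promoter region in both replicates. For distal regions raised 2.5-fold, 86.7% were recovered and 0% of unchanged lists were called. The simulated genes had more distal regions than the 0.0998 per coding gene that both replicates shared. This recovery therefore does not carry over to the thresholded lists. The test of promoter regions lacking in replicate 2 recovered 63.3% of planted lists and called 1.25% of unchanged ones. Its simulated lists kept most of their genes. The real lists had as few as 1 gene with a region in replicate 1, so this recovery can be too high. All 5 motifs planted in 5% of windows were recovered, with 0 of 26 others called. Both simulated window sets were drawn from the same chromosome, while summits and flanks can differ in base composition. The simulation therefore does not show how often such a difference gives a call. Matches to the mitochondrial genome needed at least 90% identity over at least 50% of the region. The tools were Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, pysam 0.24.0 and matplotlib 3.10.9, samtools 1.23.1, bedtools 2.31.1 and blastn 2.17.0.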

Results

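Open chromatin was measured by ATAC-seq, in which a transposase cuts accessible DNA and inserts sequencing adapters, in limb tissue of B6NCrl mouse embryos at embryonic day 13.5. The design held 1 group with 2 biological replicates, each made from its own biosample of pooled male and female embryos and carrying the same donor label. No other tissue, stage or treatment was part of the design. The comparisons were therefore between the replicates, between locations in the genome, between gene lists and the remaining protein-coding genes, and between peak summits and flanking DNA. Coordinates are on mm10 (GRCm38) and count from 1. Each peak carried the authors' own enrichment value, and the peak lists gave no read counts, so the depth of each library was unknown. The p-values over genes, regions and windows describe these 2 libraries, since genes, regions and windows are not replicates.

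The replicates found largely the same open regions, and replicate 1 found more of them. Replicate 1 had 17459 regions covering 16.2 Mb (median length 914 bp), and replicate 2 had 12570 regions covering 10.9 Mb (median length 854 bp). Of the replicate 2 regions, 93.4% (11737) overlapped a region of replicate 1. In the other direction, 66.6% (11633) of the replicate 1 regions overlapped a region of replicate 2. In 100 random placements of the other list on the same chromosomes, the highest overlaps were 1.43% and 1.07%. The covered bases had a Jaccard index of 0.581. Across the 11633 pairs of overlapping regions, the enrichment values had a Spearman rho of 0.874 and a Pearson r of 0.864 on the log2 scale. These correlations are across regions within 1 pair of libraries, and regions are not independent replicates. When the strongest regions of replicate 1 were taken in equal number to those of replicate 2, the overlaps were 80.8% and 81.6%.

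Regions found in replicate 1 alone were weaker and lay less often at promoters. The 5826 regions of replicate 1 without a partner had a median enrichment of 6.39, against 10.4 for its shared regions. Promoters held 37.4% of the former and 81.3% of the latter. The 833 regions found in replicate 2 alone had a median enrichment of 5.63, with 35.3% at promoters.

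Promoters made up most of the open regions. A region was assigned to a promoter when its strongest summit lay within 1000 bp of an annotated transcription start site, and these windows cover 5.88% of the genome. Promoter regions were 66.7% of the list in replicate 1 and 78.3% in replicate 2, a mean of 72.5% ± 8.24 (SD, n = 2), which is 12.3-fold over the promoter share of the genome. Introns held 12.2% ± 3.8 (SD, n = 2) of the regions and 37.3% of the genome. Intergenic DNA held 13.8% ± 4.07 (SD, n = 2) of the regions and 53.7% of the genome. Exons outside promoter windows held 1.48% ± 0.37 (SD, n = 2). The share depended on the list: in the looser pseudoreplicated lists, 37.5% of the regions were at promoters.

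**Figure D1:**
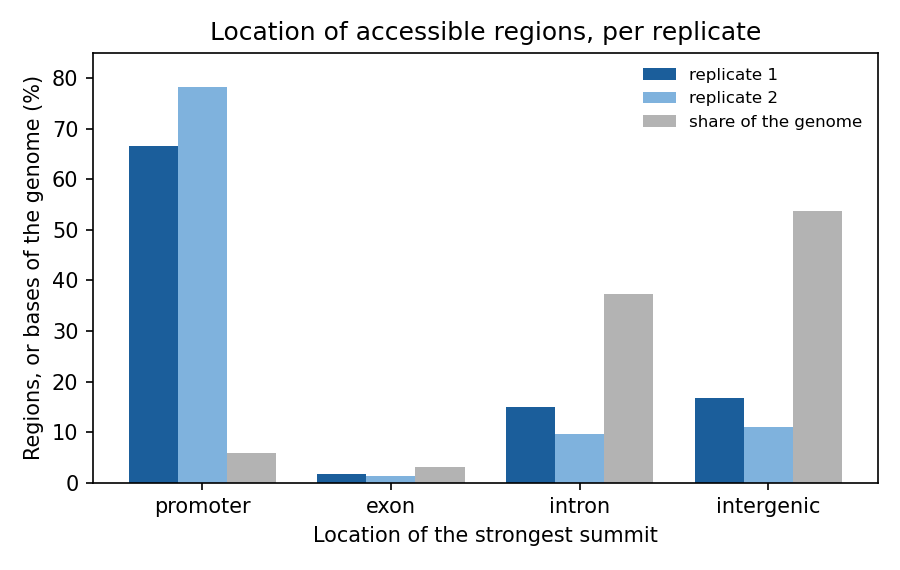
Share of accessible regions by the location of the strongest summit (vertical axis, percent) at promoters, exons, introns and intergenic DNA, for replicate 1 (dark bars) and replicate 2 (light bars), beside the share of the genome in each location (grey bars). Promoters hold 66.7% and 78.3% of the regions and 5.88% of the genome.

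Promoter regions were also stronger than distal regions in both replicates. Each region carried the value of its strongest summit, and the number of summits per region was not taken into account. In replicate 1, the median log2 enrichment was 3.34 over 11640 promoter regions and 2.77 over 5819 distal regions. In replicate 2, it was 3.14 over 9845 promoter regions and 2.70 over 2725 distal regions. The difference was 0.57 and 0.44 on the log2 scale (two-sided permutation test over regions within each replicate, p = 1e-05 in both, the smallest that 100000 resamples can give), a mean of 0.51 ± 0.09 (SD, n = 2).

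Genes used by nearly every cell had open promoters far more often than other genes. A promoter region was present in both replicates at 9974 of the 21728 protein-coding genes (45.9%), and at 23 of the 26 housekeeping genes (88.5%; Fisher's exact test, odds ratio 9.05, adjusted exact p = 0.000127 over 18 lists). By enrichment in the pooled libraries, the strongest of these were at Rplp0, a protein of the large ribosomal subunit (16.4 pooled, 16.1 and 13.8 in replicates 1 and 2), Vcp, an ATPase of protein quality control (15.6 pooled, 15.7 and 14.4), and Tfrc, the transferrin receptor (15.2 pooled, 15.2 and 11.2). The 3 housekeeping genes without a promoter region in replicate 2, named after their values were seen, were Ubc, Psmb4 and Gpi1.

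Genes of limb outgrowth and patterning were mixed. Of 33 such genes, 13 had a promoter region in both replicates (39.4%), against 45.9% of other genes, and the list did not pass the test (Fisher's exact test, adjusted exact p = 0.518). The share depended on the replicate: 21 genes (63.6%) had one in replicate 1, against 53.4% of all coding genes, and 13 (39.4%) in replicate 2, against 46.7%, and neither passed (adjusted exact p = 0.332 and 0.514). The strongest were at the Iroquois homeobox gene Irx5 (enrichment 12.1 and 10.7), the T-box gene Tbx3 (11.4 and 9.24) and the basic helix-loop-helix gene Twist1 (9.51 and 9.07). Also open in both replicates were Gli3, a transcription factor of Hedgehog signalling (9.09 and 7.44), the hindlimb gene Tbx4 (7.83 and 6.85) and Hand2, a posterior limb bud regulator (4.85 and 5.01). Pitx1, which specifies hindlimb identity, and the limb mesenchyme gene Prrx1 had a promoter region in replicate 1 alone (4.92 and 4.35). Shh, the signal of the posterior limb bud, Fgf8 of the apical ectodermal ridge and Fgf10 of the limb mesenchyme had none in either replicate. The forelimb gene Tbx5, Alx4, Bmp2 and En1 also had none. Among these genes, the pooled IDR-thresholded list had a promoter region at Bmp2 alone (3.96). In the looser lists the list was above other genes: 28 of the 33 genes (84.8%) had a promoter region in both replicates, against 60.8% of other genes (Fisher's exact test, adjusted exact p = 0.00873), with Fgf10, Pitx1, Prrx1, Bmp2 and En1 among them and Shh, Fgf8, Tbx5 and Alx4 not. The list was below other genes in the stronger 50% of each list (9.09%; adjusted exact p = 0.0224) and at the gene's 5′ end alone (24.2%; adjusted exact p = 0.0483), and below random lists matched on promoter GC content (39.4% against a median of 60.6%; permutation test, adjusted p = 0.0274).

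Of the Hox genes, which pattern the body axis and the limb, the Hoxb and Hoxc genes were open less often than other coding genes, and the posterior Hoxa and Hoxd genes did not pass the test. Of the 9 genes of Hoxa and Hoxd paralog groups 9 to 13, 5 had a promoter region in both replicates (55.6%; adjusted exact p = 0.741 against other genes), and 7 had one in replicate 1 (77.8%; adjusted exact p = 0.227). The strongest were at Hoxa13 (chromosome 6, 52257694 to 52260880; enrichment 7.84 and 7.34), Hoxd10 (7.71 and 5.91) and Hoxd13 (chromosome 2, 74668310 to 74671599; 6.57 and 5.58). Hoxa11, which patterns the forearm and lower leg, and Hoxd9 had none in either replicate, though the pooled IDR-thresholded list had one at Hoxa11 (3.74). All 9 had one in both looser lists (100%; adjusted exact p = 0.0292). Of the 19 Hoxb and Hoxc genes, 2 had a promoter region in both replicates (10.5%; adjusted exact p = 0.00376), Hoxc10 and Hoxc5, and these were 1 region at a start site annotated for both genes. Hoxb1, Hoxb2 and Hoxb13 had none. The adjusted p-values here are from Fisher's exact test, and the Hox lists were not tested against each other. Beside the Hoxd cluster, Lnpk had a strong promoter region (14.8 and 14.1) and Evx2 had none.

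Counted in both replicates at the IDR threshold, bone genes had fewer open promoters than other coding genes. Cartilage, joint and tendon genes did not pass that test but were lower, as bone genes were, against lists matched on promoter GC content. The lists were not tested against each other. Of 21 cartilage genes, 5 had a promoter region in both replicates (23.8%; Fisher's exact test, adjusted exact p = 0.0626, not past the threshold), with 42.9% in replicate 1 and 28.6% in replicate 2. They included the cartilage collagen genes Col11a1 (enrichment 12.9 and 13.8) and Col9a1 (8.52 and 7.97) and Sox9, the master regulator of chondrogenesis (9.61 and 8.06). Col2a1, the main cartilage collagen gene, Acan, which encodes aggrecan, Cnmd and Col10a1 had none in either replicate. Of these, Col2a1, Acan and Cnmd had one in both looser lists, and the pooled IDR-thresholded list had one at Col2a1 (4.66) and Acan (4.10). Of 14 bone genes, 2 had a promoter region in both replicates (14.3%; adjusted exact p = 0.0388), Phospho1, a phosphatase of mineralisation (12.5 and 10.4), and the type I collagen gene Col1a1 (5.68 and 4.54). Alpl, Bglap, Dlx6 and the osteoblast regulator Runx2 had none in either replicate, though Dlx6 had one in the pooled list (5.25) and in both looser lists. The bone call was lost without replicate 1 (adjusted exact p = 0.0895) and under 6 other settings (adjusted exact p from 0.065 at the gene's 5′ end alone to 0.211 in the pooled list), and cartilage was called lower under 3 (adjusted exact p from 0.013 at the 5′ end alone to 0.0342 with a smaller gene background). Against random lists matched on promoter GC content, medians were 42.9% for bone, 57.1% for cartilage and 56.3% for joint and tendon genes (permutation test, adjusted p = 0.0265, 0.0036 and 0.0358). The looser lists did not keep this direction for cartilage (17 of 21, 81.0%) and joint and tendon genes (13 of 16, 81.25%), against 60.8% of other genes. Bone genes stayed lower there (5 of 14, 35.7%). None of the 3 passed in the looser lists (Fisher's exact test, adjusted exact p = 0.109, 0.16 and 0.133). Of 16 joint and tendon genes, 4 had a promoter region in both replicates (25%; adjusted exact p = 0.147), led by Tcf4 (12.9 and 10.3), Egr1 (11.2 and 9.54) and Osr2 (8.12 and 6.29). In replicate 1 alone 9 of the 16 had one (56.3%; adjusted exact p = 1). Lists were set by gene symbol, and the Tcf4 scored was the gene on chromosome 18 (69343356 to 69689079). Its use in joint or tendon was not checked. The joint gene Gdf5 had a promoter region in replicate 1 alone (3.75). The tendon regulator Scx, Mkx, Gdf6 and Col14a1 had none in either replicate. Of these, Scx, Mkx and Gdf6 had one in both looser lists, and the pooled IDR-thresholded list had one at Scx (3.58) and Gdf6 (5.04).

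Genes of skeletal muscle, ectoderm, vessels and blood had few open promoters. Of 23 muscle genes, 1 had a promoter region in both replicates (4.35%; adjusted exact p = 0.000127), the slow troponin gene Tnnt1 (4.43 and 4.65). Single replicates gave higher shares, 5 genes in replicate 1 (21.7%) and 3 in replicate 2 (13.04%), and the list was called lower in each (adjusted exact p = 0.00547 and 0.00263). The other 2 of replicate 2, named after their values were seen, were Actc1 and Tnni1, which had none in replicate 1. The myogenic regulator Myod1 had one in replicate 1 alone (4.98), and Myf5, Acta1, Chrna1 and Chrnd had none. Of 21 ectoderm genes, 1 had one in both replicates (4.76%; adjusted exact p = 0.000215), Irf6 (8.74 and 6.61), and 2 had one in replicate 1 (9.52%), the other being Krt10 (10.6), named after its values were seen, while Trp63, the regulator of stratified epithelium, Cdh1, Dlx3 and Epcam had none. None of the 17 endothelial genes (adjusted exact p = 0.000138), 15 red blood cell genes (adjusted exact p = 0.000276) or 16 leukocyte genes (adjusted exact p = 0.000207) had a promoter region in both replicates. Cdh5, Cldn5 and Emcn of endothelium, Alas2, Epor, Gata1 and the globin gene Hbb-bs of red blood cells, and Adgre1, Aif1 and C1qa of macrophages had none in either. The endothelial result depended on the list: in replicate 1, 5 of the 17 genes had a promoter region (29.4%), which were Kdr, Flt1, Flt4, Erg and Egfl7, chosen after their values were seen, and the call was lost without replicate 2 (adjusted exact p = 0.0743) and in the conservative list (29.4%; adjusted exact p = 0.068). Of 14 Schwann cell and melanoblast genes, 3 had a promoter region in both replicates (21.4%; adjusted exact p = 0.125): the pigment cell regulator Mitf (15.9 and 14.8), Mpz (12.1 and 9.37) and Pmel (11.3 and 6.56). The regions of Mpz and Pmel also lay at start sites of Sdhc and Cdk2, and Cdh19, Dct and Erbb3 had none. This list was called lower in the conservative list (21.4%; adjusted exact p = 0.0266) and, as an alternative added after seeing the data, with promoter regions shared between coding genes left out (7.14%; adjusted exact p = 0.0432). All p-values here are from Fisher's exact test. In the looser lists, the muscle, ectoderm and endothelial calls were lost (adjusted exact p = 0.448, 0.0723 and 0.0723), and the red blood cell and leukocyte calls held (6.85e-05 and 2.76e-06).

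Genes of organs other than the limb had fewer open promoters than other coding genes. Promoter regions in both replicates were found at 4 of 22 neuronal genes (18.2%; adjusted exact p = 0.0159), 1 of 20 liver genes (5%; adjusted exact p = 0.000296), 2 of 14 heart genes (14.3%; adjusted exact p = 0.0388), 0 of 19 lung, gut and pancreas genes (adjusted exact p = 0.000127) and 2 of 16 germ cell and photoreceptor genes (12.5%; adjusted exact p = 0.0159), all by Fisher's exact test. The neuronal regions included Syt1 (11.4 and 11.2), Elavl4 (11.7 and 9.23) and Snap25 (8.81 and 10.4), and Dlx2, Elavl3 and Eomes had none. The liver region was at Apoh, in a region that also lay at a start site of Prkca, and the heart regions were at Myl4 and Myl3, shared with Cdc27 and Pth1r. Alb, Afp and Ahsg of liver, Myh6, Myl2 and Gata4 of heart and Cdx1, Cdx2 and Cela1 of gut and pancreas had none. The germ cell and photoreceptor regions were at Dazl and Opn1sw, while Crx, Ddx4 and Gnat1 had none. In replicate 2 alone the shares were higher for liver (10%, 2 genes) and heart (28.6%, 4 genes), with Apoa1, Tbx20 and Hcn4, named after their values were seen, open in that replicate alone. The liver call held there (adjusted exact p = 0.00263), and the heart call was lost both there (adjusted exact p = 0.217) and at the gene's 5′ end alone (adjusted exact p = 0.065). The neuronal and heart calls were lost in the looser, pooled and conservative lists and in the stronger 50% (adjusted exact p from 0.0549 to 1). The germ cell and photoreceptor call was lost in the stronger 50% (adjusted exact p = 0.0782), and with promoter regions shared between coding genes left out it and the neuronal call were lost (adjusted exact p = 0.102 and 0.164).

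**Figure D2:**
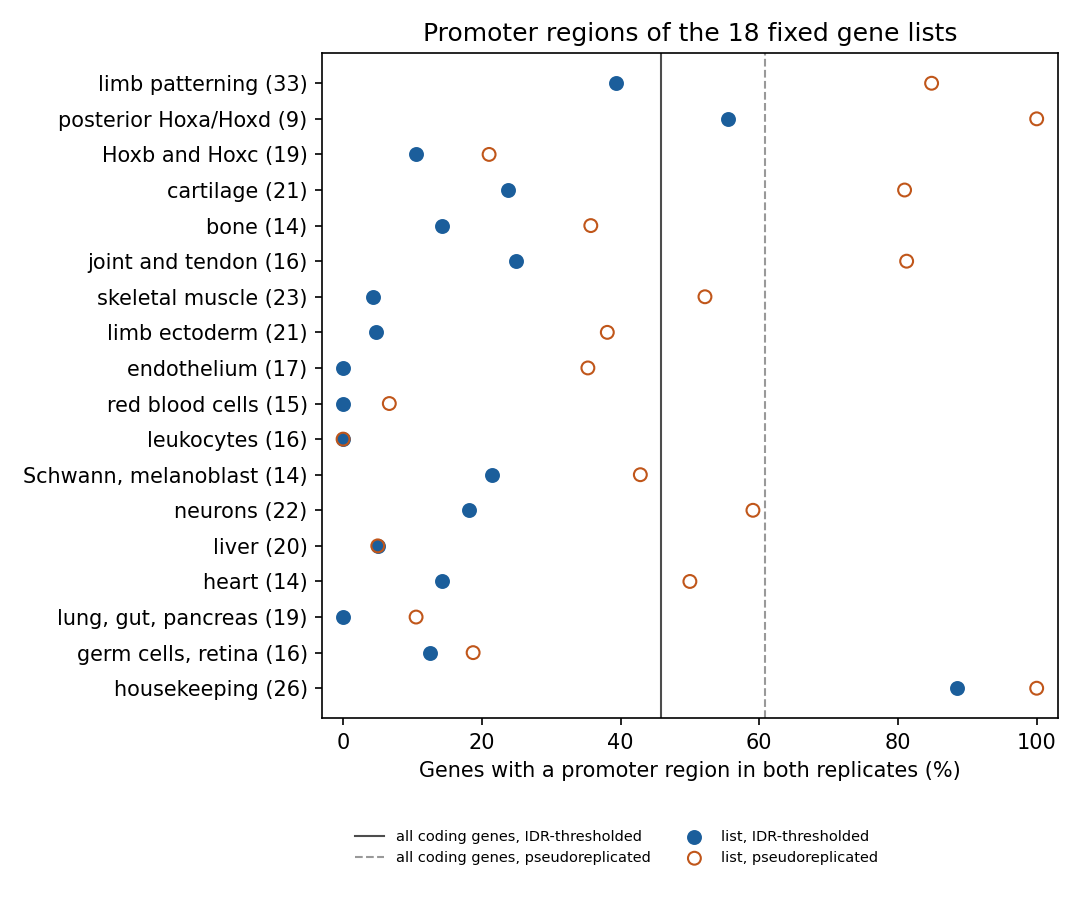
Percent of the genes of each of the 18 fixed lists (horizontal axis; number of genes in parentheses beside its name) with a promoter region in both replicates, in the IDR-thresholded lists (filled points) and in the looser pseudoreplicated lists (open points), with all protein-coding genes as the solid (45.9%) and dashed (60.8%) lines. Limb patterning genes lie at 39.4% and 84.8%, and housekeeping genes at 88.5% and 100%.

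Few genes had several distal regions nearest to them. Replicate 1 had 5819 distal regions, of which 2172 overlapped a region of replicate 2, and 92.0% of coding genes were nearest to none of them. The genes with the most were Gas1, which encodes a co-receptor for Hedgehog, and the sorting receptor gene Sorl1, with 7 each, Smad7, an inhibitor of TGF-beta signalling, with 6, and Ddc, Ebf2, Nars2 and the RNA-binding protein gene Zfp36l1 with 5 each. Actg1, Asb13 and the cyclin gene Ccnd3 had 4 each. Gli3 and Hand2 had 3 each, and Col1a1, Cdh5, Acan and Bmp2 had 2 each. Shh, Fgf8, Fgf10, Tbx5, Tbx4, Pitx1, Sox9 and Runx2 had 0 such shared regions. In the pooled IDR-thresholded list, Sox9 had 6, Tbx4 had 4, Fgf10 had 2, and Fgf8 and Pitx1 had 1 each. Shh, Tbx5 and Runx2 had 0 there. Shared regions of the looser lists ran from 1 for Shh to 7 for Tbx4 and 10 for Sox9.

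No gene list passed against random lists matched on the length of the gene's surroundings (2-sided permutation test with 10000 random lists, 0 of 18 lists at an adjusted p under 0.05 and 0 at an unadjusted p under 0.05). The replicates shared only 0.0998 distal regions per coding gene, so the test can miss lists with raised counts. Limb patterning genes had 0.394 distal regions per gene, against a median of 0.242 in matched lists (adjusted permutation p = 0.948). Cartilage genes had 0.381, against 0.143 (unadjusted permutation p = 0.0932, the lowest of the 18, adjusted permutation p = 0.948). In the pooled IDR-thresholded list, cartilage, joint and tendon, and housekeeping genes stood above matched lists (adjusted permutation p = 0.0198, 0.0108 and 0.024). Joint and tendon genes also did in the conservative list (adjusted permutation p = 0.018). In the looser lists, 15402 distal regions were shared and 4 lists stood above matched lists by the same permutation test: joint and tendon genes with 4.88 per gene against 1.56 (adjusted permutation p = 0.0036), limb patterning genes with 3.91 against 2.09 (adjusted permutation p = 0.0036), muscle genes with 1.65 against 0.652 (adjusted permutation p = 0.0156) and cartilage genes with 2.48 against 1.19 (adjusted permutation p = 0.045).

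The Shh locus had no region at the IDR threshold. The introns of Lmbr1 hold the distant limb enhancer of Shh, and Lmbr1 itself had a strong promoter region (enrichment 14.1 and 13). The summit of that region lay outside the gene, and no summit lay in Lmbr1 (chromosome 5, 29229802 to 29378390) or in Shh (chromosome 5, 28456815 to 28467256) in the thresholded list of either replicate or of the pooled libraries. In the looser lists, replicate 1 had 1 region in an intron of Lmbr1 (chromosome 5, 29314745 to 29315155, enrichment 2.28), which replicate 2 and the pooled libraries did not have. Within Shh, looser regions lay in an intron in replicate 1 (28465027 to 28465260, enrichment 3.04) and in replicate 2 (28464471 to 28464793, enrichment 2.71), and replicate 1 had another near the start of an antisense transcript (28459012 to 28459293, enrichment 3.23). Regions missing from a list can be open below its threshold.

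E-box, TEAD and CTCF motifs marked the distal summits. At distal summits, 10 of 31 consensus motifs were more frequent than in flanks 1000 bp away and 6 were less frequent, in both replicates (Fisher's exact test within each replicate, adjusted p under 0.05). The CAGCTG E-box bound by myogenic and other basic helix-loop-helix factors was in 28.4% ± 3.20 (SD, n = 2) of distal windows, against 8.66% ± 0.17 of flanks. The CATCTG E-box of TWIST and HAND factors was in 22% ± 1.91 against 14.9% ± 0.16. The TEAD motif of the Hippo pathway was in 10.9% ± 0.38 against 4.50% ± 0.68, and the motif of the insulator protein CTCF in 5.39% ± 1.13 against 0.277% ± 0.06. The SP-KLF, NFY, RFX, ETS, NRF1 and NFI motifs were also more frequent. Of these, 4 were in few of the 5819 and 2725 distal windows of replicates 1 and 2. They were ETS (33 and 20), RFX (27 and 12), NRF1 (16 and 7) and NFI (15 and 4). The GATA motif was less frequent (1.17% ± 0.25 against 4.42% ± 0.11), as were SOX, PITX, PBX-HOX, TCF-LEF and TAATTA homeodomain motifs. The HOX13 motif was in 1.60% ± 0.39 of distal windows and 1.44% ± 0.10 of flanks and did not pass (Fisher's exact test, adjusted exact p = 0.108 and 0.918 in replicates 1 and 2). Against dinucleotide-preserving shuffles of the same windows, HOX13 was higher (2.63-fold), as were AP-1 (1.54-fold), MEF2 (5.43-fold) and TAATTA (1.79-fold), the last of which was lower than in flanks. With replicate 1 alone, 15 motifs were more frequent than in flanks.

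At promoter summits, SP-KLF and NFY motifs were the most frequent. Motifs of the GC-box factors SP-KLF were in 20.8% ± 0.12 (SD, n = 2) of windows against 0.86% ± 0.02 of flanks, NFY in 17.4% ± 1.18 against 1.56% ± 0.06, the CAGCTG E-box in 11.65% ± 0.32 against 8.22% ± 0.05, ETS in 7.49% ± 0.12 against 0.242% ± 0.04, and NRF1 in 1.75% ± 0.03 against 0.00537%. In all, 10 motifs were more frequent and 17 less frequent in both replicates, and P63, GLI, NFI and HNF1 passed in neither direction. The lower calls depended on the comparison sequence: against dinucleotide-preserving shuffles of the same windows, 1 motif was lower, and SOX, HOX13, MEIS, MEF2, FOX and CArG motifs were higher. Against the same shuffles, the distal calls of CTCF (9.55-fold), TEAD (2.37-fold), CAGCTG (1.78-fold), CATCTG (1.56-fold), SP-KLF, NFY and RFX remained, and those of ETS (1.84-fold), NRF1 (7.25-fold) and NFI (7.51-fold) did not pass. The promoter calls of CAGCTG and REST and the lower distal calls other than GATA did not pass either.

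**Figure D3:**
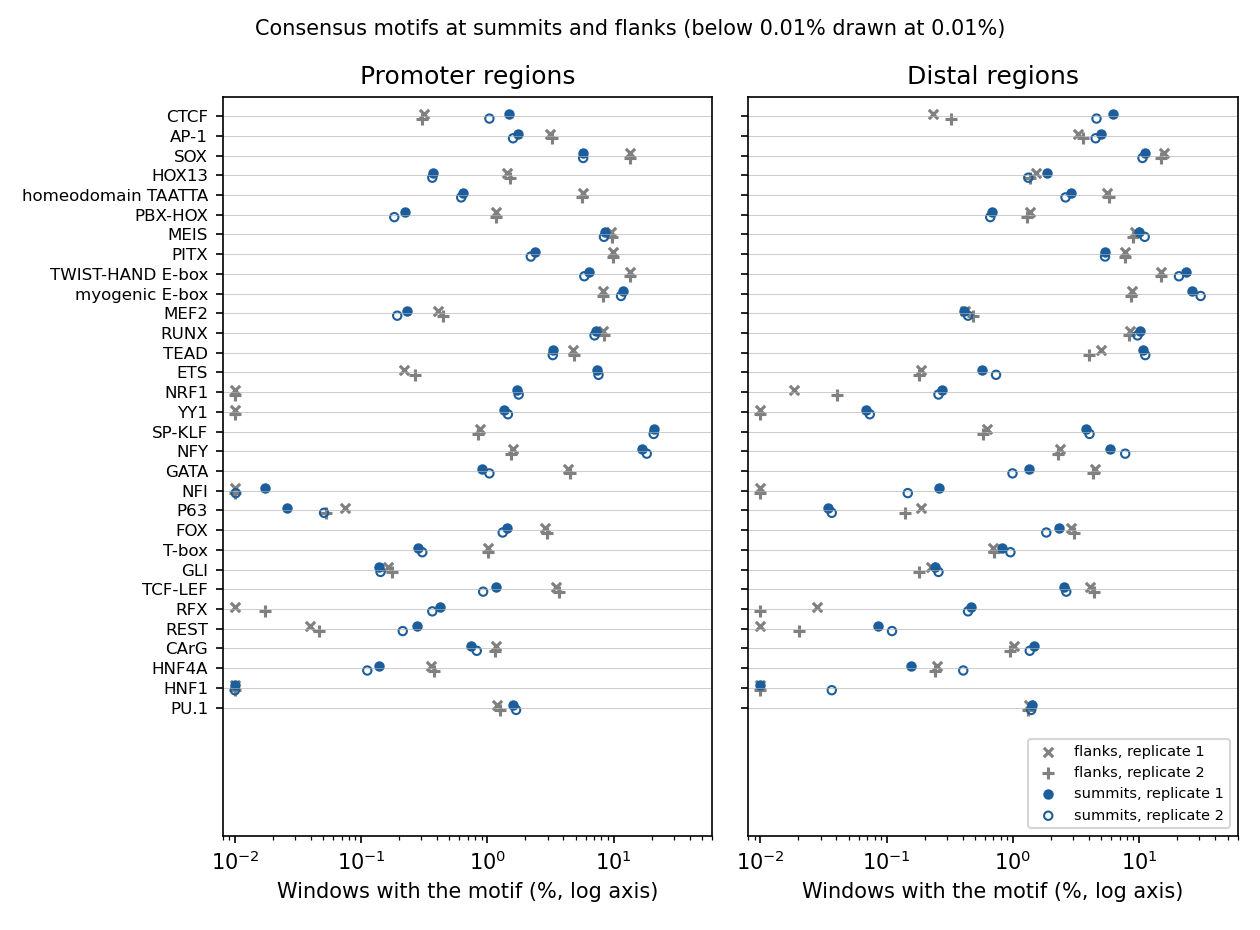
Percent of windows with each of 31 consensus motifs (horizontal axis, log scale) at summits (circles) and in flanks (crosses) of promoter and distal regions, for replicate 1 (filled circles, diagonal crosses) and replicate 2 (open circles, upright crosses), with values under 0.01% drawn at 0.01%. The CAGCTG E-box lies at 28.4% of distal summits and 8.66% of distal flanks on average.

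Open regions were sparse on the X chromosome and dense in gene-rich windows. The density on X was 0.448 ± 0.03 (SD, n = 2) of that on the autosomes, with 2.63 ± 0.44 regions per Mb (SD, n = 2), and Y had 9 regions in replicate 1 and 4 in replicate 2. X had 5.54 coding genes per Mb and 0.474 regions per coding gene, and the autosomes ranged from 0.526 on chromosome 7 to 0.908 on chromosome 18. Among autosomes, chromosome 11 was the densest (8.91 ± 1.87 regions per Mb, SD, n = 2) and chromosome 14 the sparsest (4.10 ± 1.15). The 1-Mb windows with the most regions in both replicates were chromosome 11 from 69000001 and chromosome 7 from 45000001 (37 regions each), chromosome 10 from 81000001 (36), and chromosome 10 from 80000001 and from 128000001 (34 each), each with between 49 and 67 coding genes. The windows on chromosome 7 from 127000001 and chromosome 8 from 70000001 also had 34.

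The 5 strongest peaks lay outside coding genes. The highest enrichment in the pooled list was at chromosome X, 143482934 to 143483180, in intergenic DNA 35531 bp from the start of Pak3 (54.3 in the pooled libraries, 52.4 and 50.7 in the replicates). Next came chromosome 2, 69355469 to 69355735 (50), and chromosome 2, 3964425 to 3964690 (42.2), both intergenic. Then followed chromosome 10, 96077546 to 96077953 (40.8), in an intron of a pseudogene, and chromosome 5, 60042765 to 60043140 (39.9), intergenic. These last matched the mitochondrial genome over 86.3% and 89.1% of their length, and the region from 69355469 on chromosome 2 over 48.3%. All 5 were found in both replicates.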

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

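The tests of the 10 strongest peaks and of lacking promoter regions at matched strength were chosen after the results were seen, and the other tests in this part were fixed before. The design has 1 group and so names no biological difference to test, and a difference in cell composition between the replicates was tested for 1 pattern.

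Some entries passed the IDR threshold in the ranked lists and were left out of the thresholded lists: 192 for the pooled list, 184 for the conservative list, 173 for replicate 2 and 158 for replicate 1. Of the 192, 50 lay on scaffolds outside the main chromosomes and 142 formed 67 regions on them. The one with the highest −log10 p-value, chromosome 1, 24611587 to 24616165, matched the mitochondrial genome over 100% of its length, and the next was in an intron of Chl1 (chromosome 6, 103648978 to 103649356, enrichment 42.4).

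The 5 strongest pooled peaks lay outside coding genes, and reads from mitochondrial DNA or repeats could give such peaks. Of the 5 strongest, 2 matched the mitochondrial genome over at least 50% of their length and 1 was soft-masked as repeat over at least 50%. Neither count decides, since at least 3 had been set as support and none as exclusion. The mitochondrial count also rests on the cut, because the second strongest matched over 48.3% of its length. Mitochondrial matches were concentrated at the top: 5 of the 10 strongest regions matched, against 6 of the other 20894 (Fisher's exact test, p = 3.5e-15), which is consistent with mitochondrial reads at those 5. The first and the third strongest had no mitochondrial match and were soft-masked over 29.6% and 8.27%, and what raised them stays open.

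Replicate 2 had fewer regions than replicate 1, and weaker signal under the same threshold or a difference in cell composition could give that. Of the regions found in replicate 1 alone, 85.7% were in the looser list of replicate 2, as weaker signal predicts. In 100 random placements the share was at most 2.66%. These placements kept the chromosome but not the location at promoters, so open regions can exceed them whatever the cause. Of the regions found in replicate 2 alone, 93.5% were likewise in the looser list of replicate 1. The share therefore does not single out replicate 2. Promoter regions of endothelial genes were lacking in replicate 2 more often than others (5 of 5 against 14%; Fisher's exact test, adjusted p = 0.000875), as were those of muscle, joint and tendon, and limb patterning genes (adjusted p = 0.0138, 0.0222 and 0.0222). Those regions were weak in replicate 1 (median enrichment 5.55 for endothelial genes, 10.7 for all genes), and against random genes of matched strength no list passed (permutation test, lowest adjusted p = 0.339, for endothelial genes with 100% against a matched median of 40% and a central 95% of 0% to 80%). Promoter regions of replicate 2 that replicate 1 lacked were not tested. Of 10153 genes with a promoter region in replicate 2, 9974 had one in both replicates. The counts were 1 of 3 for muscle, 2 of 4 for heart and 13 of 13 for limb patterning genes. Cell composition cannot be told apart from weaker signal here. The endothelial list lay outside its matched range without passing the adjustment, while limb patterning genes (38.1% against a matched median of 42.9%) lay inside theirs.

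Housekeeping genes had more promoter regions than other genes and 12 lists had fewer, and promoter GC content could give such a split, since the share of genes with a promoter region rose from 0.552% in the bin of lowest GC to 67.4% in the highest. Against random lists matched on promoter GC content, 1 of 1 list called higher lay above and 12 of 12 lists called lower lay below the central 95% of matched lists, which argues against GC content as the whole cause. With GC matched, limb patterning (39.4% against a median of 60.6%), cartilage (23.8% against 57.1%) and joint and tendon genes (25% against 56.3%) were also lower (permutation test, adjusted p = 0.0274, 0.0036 and 0.0358). This holds for promoter regions found in both replicates at the IDR threshold. In replicate 1 alone, without GC matching, the shares were 63.6%, 42.9% and 56.3%, against 53.4% of all coding genes. In replicate 2 alone they were 39.4%, 28.6% and 25%, against 46.7%. In the looser lists, without GC matching, their shares were 84.8%, 81.0% and 81.25%, above the 60.8% of other genes. Only limb patterning passed there (Fisher's exact test, adjusted exact p = 0.00873). The share of cells that use each gene stays open and was not tested.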

How the results depend on the processing

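The alternatives were planned before the data were examined, except for 2 added later: with every summit counted the promoter share was 77.8%, and leaving out promoter regions shared between coding genes gave 1 list higher and 10 lower. Depth limits all counts, since a region can be missing because its library was shallow. For 112 named genes, the number of replicates with a promoter region was different for 37 in the pseudoreplicated lists, 29 in the stronger 50%, 7 at the gene's 5′ end and 1 at 500 bp. The causes below were not tested, except that list length follows from how the lists were built.

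Region counts for replicates 1 and 2 were 43539 and 29114 with entries not merged, 53305 and 39101 in the pseudoreplicated lists and 8729 and 6285 in the stronger 50%. Overlap of replicate 1 and of replicate 2 was 64.0% and 88.9% with 50% reciprocal overlap, 56.2% and 78.5% in the pseudoreplicated lists, 69.3% and 96.2% in the stronger 50%, and 80.8% and 81.6% with equal numbers. Spearman's rho was 0.879 with reciprocal overlap, 0.911 with −log10 p-values and 0.826 in the pseudoreplicated lists. The promoter share was 37.5% in the pseudoreplicated lists, 88.8% in the stronger 50% and 60.4% in the pooled list, and between 66.7% and 78.3% with each replicate alone. The X density ratio was 0.327 in the pseudoreplicated lists and 0.585 in the stronger 50%. The strength difference kept its direction and side of the threshold in all alternatives. It was between 0.44 and 0.84 in log2 enrichment, and 1.24 on the unlike scale of log2 of the −log10 p-value.

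In the pseudoreplicated lists, 3 gene lists were higher and 6 lower at promoters, and limb patterning turned to 84.8%. For distal regions, the lists called higher were 4 in the pseudoreplicated lists, 3 in the pooled list (cartilage, joint and tendon, housekeeping), 1 in the conservative list (joint and tendon) and 1 with unmatched random lists (limb patterning).

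Against dinucleotide shuffles, 1 motif was lower at promoters and 1 at distal summits. The promoter ratios that turned were AP-1 1.18, SOX 1.29, HOX13 2.78, TAATTA 1.64, PBX-HOX 1.05, MEIS 1.34, MEF2 9.22, RUNX 1.02, TEAD 1.12, FOX 2.53, CArG 1.54 and HNF4A 1.16, and the distal ones were TAATTA 1.79, PBX-HOX 1.32, PITX 1.24 and MEF2 5.43. The distal MEF2 ratio was also 1.54 in the pseudoreplicated lists. Distal motifs called higher were 17 in the pseudoreplicated lists, 16 in the pooled list and 6 in the stronger 50%.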

Other observations

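The comparisons and the test in this part were all chosen after the main results were seen. Gene families differed in how often a promoter region was listed (Fisher's exact test, adjusted over 15 sets). A promoter region in both replicates was present at 70 of 79 ribosomal protein genes (88.6%), 33 of 36 genes for NADH dehydrogenase subunits (91.7%), 31 of 39 proteasome subunit genes (79.5%), 264 of 365 zinc finger genes named Zfp (72.3%) and 66 of 98 histone genes (67.3%), against 45.5% to 45.8% of other genes (highest adjusted exact p = 4.1e-05). It was present at 0 of 1134 olfactory receptor genes, 1 of 330 vomeronasal receptor genes, 0 of 53 keratin genes, 0 of 57 keratin-associated protein genes and 1 of 56 clustered protocadherin genes (highest adjusted exact p = 1.08e-13). Genes on the X chromosome had one less often than other genes (33.8% against 46.5%; adjusted exact p = 2.22e-14), with the number of X copies not taken into account.

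Genes with a promoter region in both replicates were counted in the 4 Hox clusters. Counts were 5 of 11 genes in Hoxa, 2 of 9 in Hoxd, 2 of 9 in Hoxc and 0 of 10 in Hoxb, and in the looser lists 8, 6, 3 and 1. Of these sets, Hoxb was below other genes (Fisher's exact test, adjusted p = 0.0032), and the clusters were not tested against each other. Outside the posterior Hoxa and Hoxd genes and the Hoxb and Hoxc genes, Hoxa1 (enrichment 6.21 and 5.38) and Hoxa7 (3.28 and 4.80) had a promoter region in both replicates. In the looser lists, the genes with the most distal regions in both replicates included Zfp36l1 (21), Gas1 (19), the nuclear factor gene Nfib (18), the axon guidance receptor gene Robo1 (17), and Gli3, Rybp and Smad7 (16 each).

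Limb patterning genes were called above other genes at promoters in the looser lists alone. One hypothesis is that their promoter regions are present but weak, as they may be if only some limb cells use each gene. In the looser lists, the mean log2 promoter enrichment of the 28 limb patterning genes was 2.40 in replicate 1, against a median of 3.23 in random lists of genes with a promoter region, and 2.28 against 2.94 in replicate 2 (permutation test, larger adjusted p = 0.00068). This does not decide the hypothesis, because the outcome was close to fixed by the pattern itself: 13 of those 28 genes also passed the IDR threshold in both replicates (46.4%), against 75.5% of all genes with a promoter region in both looser lists. Nor was weakness particular to them: 10 of the 17 lists tested were below random lists in both replicates, among them muscle, ectoderm and neuronal genes, which were not above other genes in the looser lists. How many cells carry these regions was not tested.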
